A study of Chlamydomonas reinhardtii with 6 samples.

How the data were processed

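Cultures of Chlamydomonas reinhardtii strain CC-125 were kept as 15 mL dishes, 2 mL were sampled after 1 h with UV-B passed or blocked, and libraries were made from 400 ng of total RNA with a stranded mRNA kit, per the labels' protocols. Per the submitters' processing notes, TopHat2, HTSeq 0.5.3p9 and edgeR 3.4.2 were used by the authors; the genome build, the gene models and the strand setting of the counting are not given in the sources used here. The authors deposited, per the file headers and file contents, a table of normalised values for 13452 genes in 6 libraries. These values are a signal per gene, CPM-like: read counts divided by an effective library size, meaning a library total multiplied by a normalization factor of the authors. Column totals therefore differ between libraries. The authors also deposited a table of 2596 genes with log2 fold changes, log2 CPM, p-values and false discovery rates of their own comparison, together with gene descriptions and functional categories. The smallest absolute log2 fold change in the deposited table is 1.00, and 1 gene has a false discovery rate above 0.05, of 0.056.

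Each column was matched to its sample through the description label and title. The column names of the no UV-B libraries carry only the letters UVB and a number, and the labels give those names to the samples whose titles and treatment say no UV-B. Groups came from the titles. No column of per-sample values was left unused (0 columns).

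Every deposited value was a whole multiple of the value of 1 read in its library to within 0.001 reads (100% of values in each of the 6 libraries), with 1 read worth 0.0828 to 0.132. In 1 library, no UV-B replicate 3, no gene has exactly 1 read (0 genes), and the step was taken from the common spacing of its values. Recovered totals ran from 7868534 to 11972794 reads, with a median of 97 reads per gene and library. Normalization factors were 0.926, 0.963 and 1.00 in the no UV-B libraries and 1.02, 1.02 and 1.08 in the UV-B libraries, so the groups did not overlap in this factor. The 20 most abundant genes took 14.6% to 16.8% of reads per library. A gene has at least 45 reads over the 6 libraries, so genes with fewer reads lie outside the table and are not analysed here. Counting error limits the values of low genes, and intervals cover counting error only.

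The design was fixed before the data were examined. Because the values are normalised and not counts, the main test was limma 3.58.1 with a mean-variance trend in R 4.3.3, on log2(value + 1), for 13415 genes with a value of at least 1 in at least 3 libraries, comparing 3 UV-B with 3 no UV-B libraries without further terms. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors are limma's moderated ones (median 0.14 on the log2 scale). Python 3.11.15 with pandas 2.3.3 and SciPy 1.17.1 served for the other tables.

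Alternatives were other pseudocounts (0.1, 0.5 and 5), no filter or a minimum value of 5, rescaling by TMM, median-of-ratios size factors, quantile normalization or an equal total, limma without a trend, with sample weights or with robust moderation, the replicate number as a covariate, each library left out in turn, an adjusted p under 0.01, and list membership by symbol alone. On the recovered reads, edgeR 4.0.16 (quasi-likelihood) called 7943 genes and DESeq2 1.42.0 called 6832, against 7920 in the main test. The edgeR log2 fold changes differed from those in the authors' table by a median of 0.0060 in absolute value.

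For lists, 26 sets of gene symbols and description words were fixed before the data were examined. Descriptions and symbols were found only in the authors' table, where 540 genes have a description, 884 a functional category, 34 a symbol, and 1033 (39.8%) an informative text of either kind. The RefSeq gene table for assembly Chlamydomonas_reinhardtii_v5.5 matched 9922 of the 13452 identifiers (73.8%) and gave 0 symbols, so it was used only for which genes neighbour each other. Since listed genes are those called by the authors, tests that set a list against all genes (camera and fry) were not run, as the design provided for this case. The direction of list members was compared with that of the other annotated genes by a two-sided Fisher's exact test for the 14 lists with at least 5 members. Of the others, 2 lists had no member and 10 had fewer than 5. The exact test was added after the annotation had been seen. Some matches come from words alone, such as sugar phosphate transporters, starch phosphorylase and phosphate acetyltransferase in the sulfur and phosphate list. Where a gene has no description, its stated function rests on the rest of that annotation, mainly the functional category, and was not checked.

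Named genes followed a fixed rule: the 8 largest rises and 8 largest falls among annotated genes past the threshold with no overlap between groups and a mean of at least 10 in 1 group; up to 3 members of each list with the smallest adjusted p; photolyases, early light-inducible proteins, UVR8, COP1, SPA1, HY5, LHCSR1, LHCSR3, PSBS1 and PSBS2 where the annotation names them; and at most 2 unannotated genes in each direction. The gene g9603 and the members of functional categories and of the anaerobic metabolism group in the closing section were chosen after their values were seen.

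Replicates were checked for duplicates by a chi-square comparison of recovered reads over genes with at least 20 reads, which gave 3.22 to 6.78 per gene and degree of freedom within groups, so no pair of libraries agreed within sampling noise. The tests were tried on simulated data with the library sizes and means of this comparison. Dispersions were those fitted to each gene (common dispersion 0.0050). There were 200 changed genes, some of which fell below the filter that kept 13292 genes. The data hold far more calls (7920), which alters the Benjamini-Hochberg adjustment, so the shares called in the simulation need not hold in the data. limma called 55.2% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 100% of those changed 4-fold, with 14 unchanged genes among 177 calls. The exact test of direction gave an unadjusted p under 0.05 for 6.4% of 500 random lists of 12 annotated genes. It did so for 68.8% of 500 lists whose 12 genes were each drawn as raised with a chance of 90%. A list of this size can thus miss such a direction even before adjustment. Random lists do not copy likeness between genes of a pathway, so its effect on the test was not tried.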

Results

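RNA was sequenced from 6 cultures of the wild-type strain CC-125 (137c mt+) of Chlamydomonas reinhardtii, a unicellular green alga used to study photosynthesis and cilia. The cultures were stationary and grew in deep petri dishes in an acetate-containing medium (TAP). They stood in weak light of 3.6 µmol m-2 s-1 beside narrowband UV-B lamps giving 0.07 mW/cm2. In 3 cultures a filter with its transmission edge at 311 nm let UV-B reach the cells, and in 3 others a filter with its edge at 360 nm blocked it. Cells were collected after 1 h, and the comparison asks which transcripts change within 1 h of UV-B in a study of acclimation. The 3 cultures of each group are described as independent, so the replicate spread includes variation between cultures. Reads assigned to the genes of the table numbered 9846545, 7868534 and 11972794 in the no UV-B libraries and 10409016, 9529134 and 11214409 in the UV-B libraries. Values are normalised read counts on a CPM-like scale, relative to an effective library size. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values.

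The largest rises of all genes tested were in PSBS2 and PSBS1, genes of photoprotection. PSBS2 (Cre01.g016750), which encodes the PsbS protein of photosystem II that acts in the dissipation of excess light energy as heat, rose from a normalised read count of 1.23 ± 0.982 to 359 ± 55.3 (mean ± SD, n = 3 per group), a log2 fold change of 7.41 ± 0.17 (SE; limma adjusted p = 4.5e-25). PSBS1 (Cre01.g016600) rose from 0.127 ± 0.125 to 158 ± 32.5, a log2 fold change of 7.13 ± 0.14 (adjusted p = 2.07e-26). The genes for the LHCSR proteins, light-harvesting-like proteins needed for energy dissipation in this alga, rose as well. LHCSR1 (Cre08.g365900) went from 670 ± 82.4 to 5239 ± 580. The largest fall of all genes tested on this scale was in a hybrid-cluster protein gene (Cre09.g391650). That rank did not hold in every setting. Over the alternatives the log2 fold change of Cre09.g391650 ran from -6.20 to -3.10 and that of Cre06.g296700 from -4.69 to -4.31. Among the next largest falls was a hydrogenase assembly factor gene (Cre06.g296700), which went from 514 ± 27.0 to 21.3 ± 4.14, a decrease of 24.1-fold in the means.

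Of 13415 genes tested, 7920 (59.0%) passed an adjusted p of 0.05, with 3955 raised and 3965 lowered by UV-B. The near-equal numbers depend on the scaling: with libraries scaled to an equal total, 4533 genes were raised and 3187 lowered. Most changes in the main test were small, since 6169 of the 7920 genes changed by less than 2-fold. The median absolute log2 fold change of the 7920 genes was 0.65. At least a 2-fold change was seen in 882 raised and 869 lowered genes, and at least a 4-fold change in 106 raised and 178 lowered genes. These 2-fold counts depend on how low values are treated: they were 453 raised and 489 lowered with a pseudocount of 5 in place of 1, and 1299 raised and 1286 lowered with edgeR on the recovered reads, the ends of their range over the settings tried. The values of the groups did not overlap in 8482 genes (63.2%), where chance alone gives 10%. Raised genes took 13.2% ± 0.707 of the reads in the no UV-B libraries and 24.6% ± 0.428 in the UV-B libraries (mean ± SD, n = 3), and lowered genes took 47.8% ± 0.558 and 35.5% ± 0.804. Correlations of log2 values ranged from 0.991 to 0.993 between libraries of a group and from 0.924 to 0.933 between libraries of different groups, across genes, which are not independent replicates. The first principal component held 86.1% of the variance and separated the groups. The filters differ in all light between 311 nm and 360 nm, so the comparison is of light passed by the filters and includes that range.

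**Figure D1:**
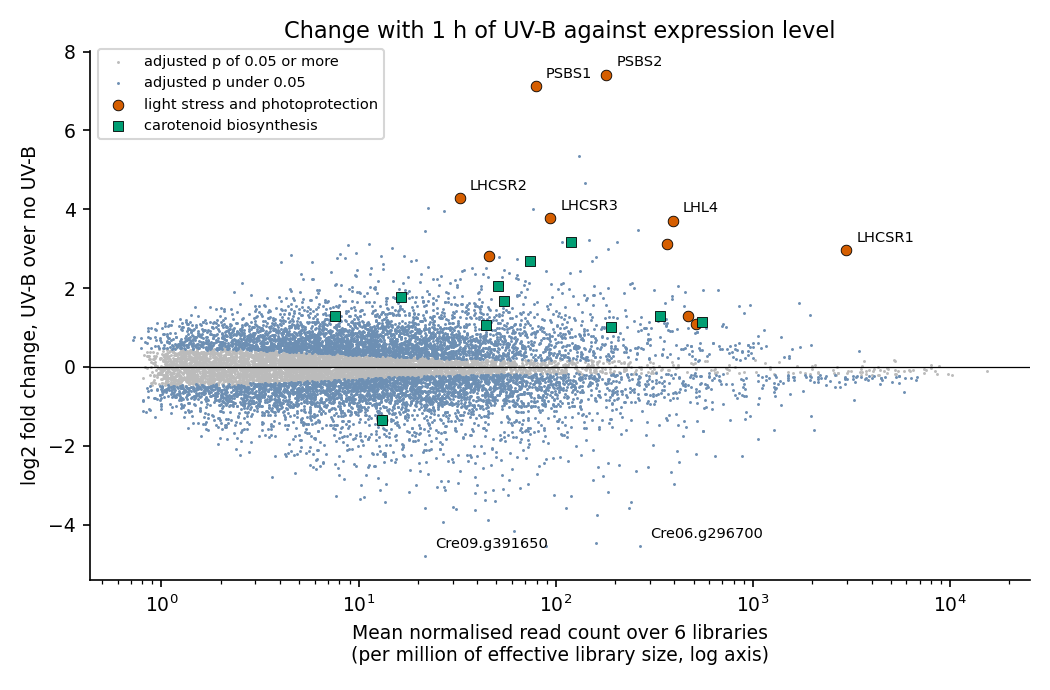
Log2 fold change of UV-B over no UV-B (vertical axis, on the log2(value + 1) scale) against the mean normalised read count over the 6 libraries (horizontal log axis) for the 13415 tested genes, with genes past an adjusted p of 0.05 in blue, members of the light stress and photoprotection list as orange circles and members of the carotenoid list as green squares. PSBS2 at 7.41 and PSBS1 at 7.13 lie highest, and the 1 lowered member of both lists, at -1.34, is drawn as a square.

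Among the 8 largest rises of annotated genes, 5 were PSBS2, PSBS1, LHCSR2, LHCSR3 and LHL4. LHCSR2 (Cre08.g367500) rose from 2.26 ± 0.222 to 62.8 ± 7.89, a log2 fold change of 4.28 ± 0.12 (adjusted p = 6.14e-23). LHCSR3 (Cre08.g367400) rose from 11.9 ± 1.22 to 176 ± 27.0, a log2 fold change of 3.77 ± 0.10 (adjusted p = 5.71e-24). LHL4 (Cre17.g740950), annotated as a light-harvesting-like gene induced by strong light, rose from 54.8 ± 7.05 to 728 ± 64.6, a log2 fold change of 3.71 ± 0.08 (adjusted p = 3.78e-25). The other rises were in FAS2 (Cre12.g492650), a fasciclin-like protein gene that went from 43.0 ± 8.59 to 480 ± 34.6, in Cre06.g258600, which went from 21.0 ± 3.71 to 194 ± 14.2, and in a putative beta-carotene hydroxylase gene (Cre04.g215050), which went from 23.3 ± 0.893 to 216 ± 12.7. Large rises were also seen in a pair of genes without informative annotation, with log2 fold changes of 5.36 ± 0.20 for Cre07.g320400 and 4.67 ± 0.11 for Cre07.g320450. PSBS1 had 4 reads over the 3 no UV-B libraries and 5097 over the UV-B libraries. The ratio of these pooled reads, each relative to effective library size, was 1130. Its exact 95% interval of 441 to 4150 covers counting error only. How reads of near-identical copies were assigned is not given in the sources used here, so the division of signal within the pairs PSBS1 and PSBS2, and LHCSR2 and LHCSR3, is uncertain.

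The 8 largest falls of annotated genes included 3 genes tied to hydrogen and anaerobic metabolism. A hybrid-cluster protein gene (Cre09.g391650) went from 42.9 ± 1.42 to 0.584 ± 0.10, a log2 fold change of -4.79 ± 0.14 (adjusted p = 1.71e-22). The hydrogenase assembly factor Cre06.g296700 had a log2 fold change of -4.54 ± 0.09 (adjusted p = 3.23e-26). An adjacent iron hydrogenase assembly gene (Cre06.g296750) went from 118 ± 4.46 to 5.70 ± 1.40, a log2 fold change of -4.17 ± 0.11 (adjusted p = 1.49e-23). A formate and nitrite transporter gene (g4546) fell from 73.2 ± 3.05 to 5.04 ± 1.18. Genes placed among the oxidases fell from 85.6 ± 3.30 to 4.85 ± 0.754 (g11012) and from 303 ± 4.15 to 21.9 ± 4.56 (Cre10.g443050). Cre16.g678200, categorised under lactoylglutathione lyase and threonine degradation, fell from 56.4 ± 3.81 to 3.88 ± 0.331. Cre17.g715200, categorised under leucine-rich repeat receptor kinases, fell from 25.8 ± 2.80 to 1.49 ± 0.284. Genes without informative annotation that fell the most were Cre16.g680700, with a log2 fold change of -4.53 ± 0.11, and g2862, with -4.47 ± 0.11.

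**Figure D2:**
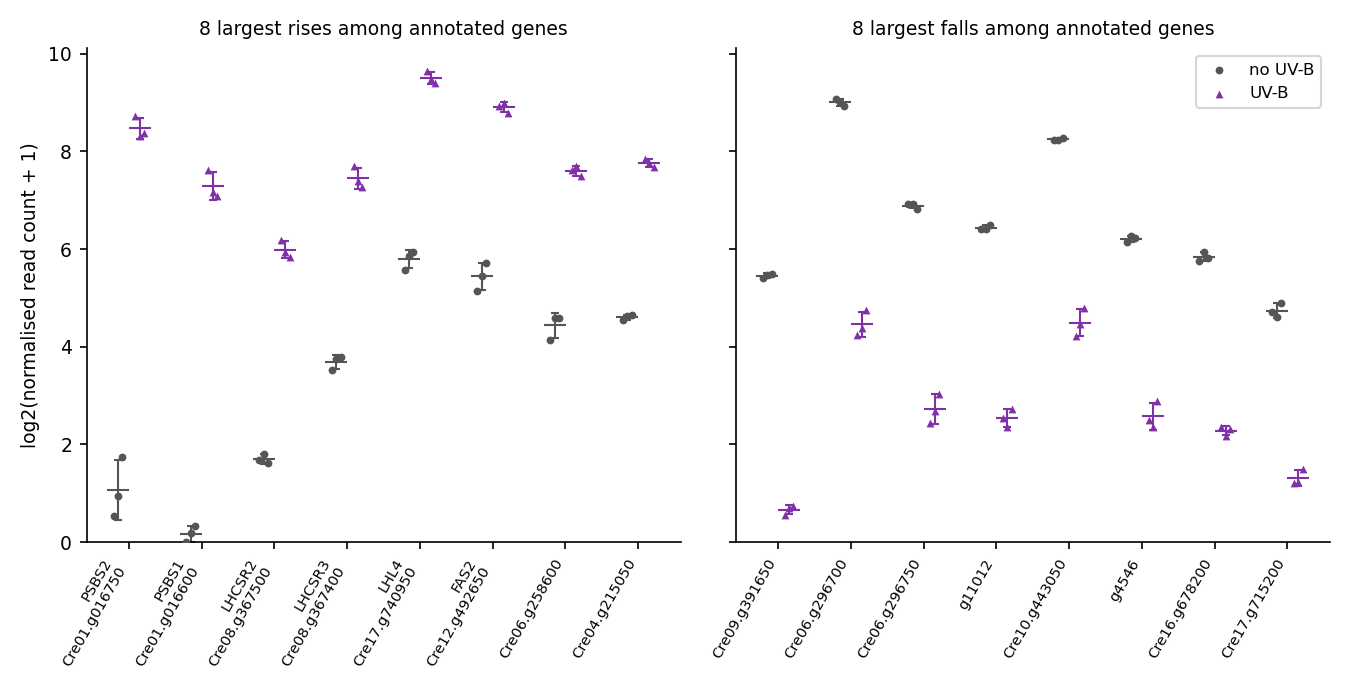
Log2(normalised read count + 1) in each of the 6 libraries (grey circles, no UV-B; purple triangles, UV-B) for the annotated genes with the 8 largest rises (left) and the 8 largest falls (right), with horizontal dashes for group means and bars for the SD (n = 3). The groups do not overlap in any of the 16 genes, and PSBS1 has 0, 1 and 3 reads in the no UV-B libraries.

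Photoprotection and pigment genes moved upward in most of the annotated cases. In the light stress and photoprotection list 10 of 11 genes rose and 1 fell, with 11 past the threshold both over all genes and adjusted over the list alone. Beside the genes above, the early light-inducible protein genes ELI3 (g9779), ELI1 (Cre16.g679250) and ELI2 (g9747), members of a family induced by light stress, had log2 fold changes of 3.12 ± 0.08, 2.82 ± 0.10 and 1.10 ± 0.07. The member that fell, by 1.34 on the log2 scale, is a gene related to violaxanthin de-epoxidase (g9603) that also belongs to the carotenoid list. In the carotenoid biosynthesis list 10 of 11 genes rose. The raised members include a pair of genes described by carotenoid cleavage and not synthesis (Cre16.g657800 and Cre16.g657750), which match by a word. The largest of these rises was in the beta-carotene hydroxylase gene Cre04.g215050, at 3.16 ± 0.08. Next came a gene categorised under phytoene dehydrogenase (Cre13.g587500), at 2.70 ± 0.09, and a carotenoid cleavage dioxygenase gene (Cre16.g657800), at 2.06 ± 0.09. The tocopherol and quinone list had 5 raised genes of 5. The largest log2 fold change was 2.49 ± 0.14 in a ubiquinone biosynthesis protein gene (Cre10.g429800), from 3.33 ± 0.414 to 23.4 ± 2.96. A gene categorised under tocopherol methyltransferase (Cre14.g624350) went from 129 ± 5.61 to 501 ± 23.9. A homogentisate solanesyltransferase gene (Cre06.g283750) went from 53.9 ± 6.89 to 190 ± 4.39. In the tetrapyrrole list 5 of 6 genes rose. They include CHLH1 (Cre07.g325500), a subunit of magnesium chelatase in chlorophyll synthesis, from 449 ± 25.3 to 964 ± 69.3, and CPX1 (Cre02.g085450), coproporphyrinogen oxidase, from 45.0 ± 4.81 to 110 ± 10.5. All 4 members of the antenna list rose, 3 of them being the LHCSR genes. All 3 members of the photosystem list rose, namely both PSBS genes and the photosystem II subunit 28 gene (Cre10.g440450), from 172 ± 11.4 to 606 ± 41.6.

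These lists can only hold genes that the authors' deposited table lists as changed more than 2-fold, because gene descriptions come from that table, so the number of members past the threshold is no independent evidence of a response. What can be tested is direction, by comparing raised and lowered members with the other annotated genes of that table. Such a test counts genes as independent, so its p-values may be too small. By Fisher's exact test, the light stress list had 90.9% raised against 54.1% of the others (p = 0.0147, adjusted p = 0.103 over 14 lists), and the carotenoid list had the same shares and p-values. For tocopherol and quinone synthesis the adjusted p was 0.246 and for tetrapyrroles 0.448, so no list passed the threshold of 0.05 for direction. This call changed with membership by gene symbol alone, where the light stress list had 46.0 percentage points more raised genes than the others (adjusted p = 0.00258 by the same exact test). Only 1 list has 5 or more members by symbol, so there the adjustment is over 1 list. In the settings with full membership the light stress list's adjusted p lay between 0.102 and 0.203.

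**Figure D3:**
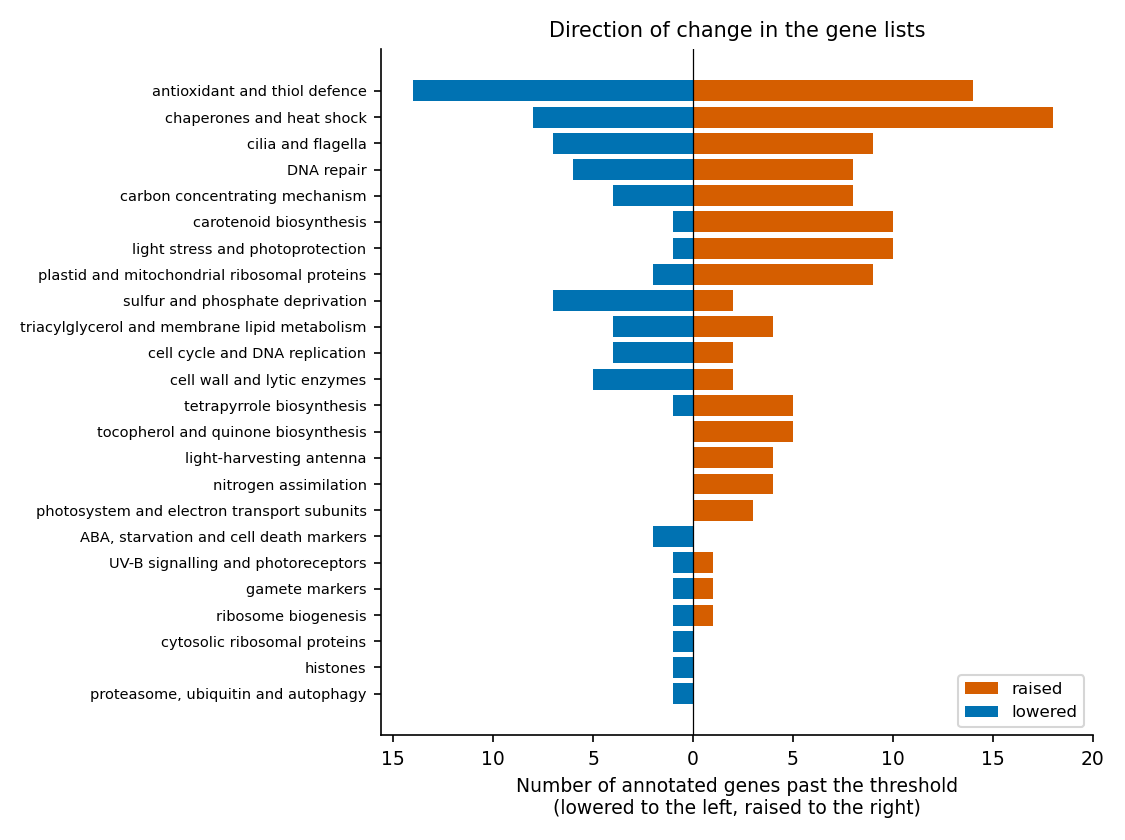
Number of annotated genes past an adjusted p of 0.05 that were raised (orange, to the right) or lowered (blue, to the left) by UV-B in each gene list with at least 1 member. Light stress and photoprotection and carotenoid biosynthesis each show 10 raised genes and 1 lowered, and antioxidant and thiol defence shows 14 of each.

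Genes of photoreceptors and DNA repair went both ways. The 2 members of the photoreceptor list are annotated as cryptochromes, flavoproteins that sense blue light, and g6392 rose from 11.4 ± 1.23 to 36.3 ± 2.13 while Cre06.g295200 fell from 61.1 ± 2.77 to 29.6 ± 1.99. UVR8, COP1, SPA1 and HY5, the named parts of UV-B signalling in plants, are not named in the annotation used here, and no values are given for them. In the DNA repair list 8 of 14 genes rose and 6 fell (adjusted p = 1 by the exact test of direction), with 14 past the threshold adjusted over the list alone. The largest rise of that list was g1436, which carries a DNA photolyase domain, the domain of enzymes that repair UV-induced pyrimidine dimers with light. It went from 20.4 ± 2.54 to 107 ± 0.705, a log2 fold change of 2.33 ± 0.09 (adjusted p = 4.85e-20). Cre16.g664350, categorised under DNA repair, rose from 32.6 ± 0.289 to 71.3 ± 1.97. The raised members of the list also include g6392 above, which is described as a cryptochrome and categorised under DNA repair.

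Stress-defence genes were divided. In the antioxidant and thiol list 14 of 28 genes rose and 14 fell (exact test adjusted p = 0.894), with 28 past the threshold adjusted over the list alone. A gene placed under ascorbate by its category (Cre13.g588150, GDP-L-galactose guanyltransferase) rose from 41.0 ± 8.04 to 327 ± 18.3. A glutathione peroxidase gene (Cre03.g197750) rose from 40.2 ± 9.25 to 281 ± 10.7. Cre16.g678200, categorised under lactoylglutathione lyase, fell by 3.56 on the log2 scale. Among chaperones and heat shock genes 18 of 26 rose and 8 fell (adjusted p = 0.379, exact test), with 26 past the threshold adjusted over the list alone. The gene for heat shock protein 70B (Cre06.g250100), a chloroplast chaperone, rose from 226 ± 7.44 to 884 ± 58.4. That for heat shock protein 70A (Cre08.g372100), a cytosolic chaperone, rose from 46.9 ± 2.17 to 188 ± 11.4. In contrast, the ClpD chaperone gene (Cre10.g465550) fell from 178 ± 5.88 to 17.8 ± 2.55, a log2 fold change of -3.26 ± 0.09. Both genes described as alternative oxidases in the starvation and cell death list fell, Cre09.g395950 from 80.6 ± 7.42 to 13.5 ± 2.24 and Cre07.g350750 from 443 ± 3.80 to 133 ± 16.5. The functional categories place the former in mitochondrial electron transport and the latter under chlororespiration in the light reactions of photosynthesis.

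Carbon and nutrient uptake genes shifted in both directions. The list for the carbon concentrating mechanism, which raises carbon dioxide around Rubisco, had 8 raised and 4 lowered genes of 12 (adjusted p = 0.787, exact test). A low-CO2-inducible chloroplast envelope protein gene (Cre04.g222750) rose from 1.55 ± 0.382 to 17.7 ± 1.56 and CAH3 (Cre09.g415700), a carbonic anhydrase of the thylakoid lumen, from 174 ± 4.71 to 540 ± 25.9. CAH6 (Cre12.g485050), another carbonic anhydrase, fell from 376 ± 5.36 to 174 ± 6.96. All 4 genes of the nitrogen list rose. LCIA (Cre06.g309000), an anion transporter shared with the carbon list, went from 4.89 ± 1.64 to 24.9 ± 1.23, and the other 3 are annotated as ammonium transporters, such as Cre13.g569850, from 0.746 ± 0.190 to 4.26 ± 0.695, and Cre09.g400750, from 3.24 ± 0.779 to 7.48 ± 0.450. In the sulfur and phosphate list 2 genes rose and 7 fell (adjusted p = 0.246, exact test), but 5 of the 7 lowered members match by a word or symbol without being genes of sulfur or phosphate uptake. These are a triose phosphate transporter gene (Cre08.g379350, from 62.4 ± 2.86 to 12.1 ± 1.73), a pair of hexose phosphate transporter genes (Cre16.g688850 and Cre10.g435650), the starch phosphorylase PHOA and the phosphate acetyltransferase PTA1. The sulfate and phosphate transporter genes themselves went both ways, 2 up and 2 down. A sulfate transporter gene (g9987) fell from 17.1 ± 0.814 to 2.19 ± 0.410, and a sodium-dependent phosphate transporter gene (Cre08.g379550) rose from 68.7 ± 6.96 to 244 ± 6.45. In the lipid list 4 genes rose and 4 fell (adjusted p = 1, exact test). A chloroplast omega-3 fatty acid desaturase gene (Cre01.g038600) rose from 189 ± 10.2 to 712 ± 18.9. A linoleate desaturase gene (Cre01.g037700) rose from 78.7 ± 6.26 to 269 ± 22.5, and BTA1 (Cre07.g324200), which makes the betaine lipids of this alga, from 9.27 ± 1.72 to 42.1 ± 4.13.

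Growth-related lists had few annotated members and no common direction. Of the plastid and mitochondrial ribosomal protein genes 9 of 11 rose (adjusted p for direction = 0.246, exact test). The 9 are all described as mitochondrial, although the functional category of S11 (Cre06.g288400) is that of a chloroplast subunit. Among them, the gene for protein S9 (Cre02.g106750) had a log2 fold change of 0.96 ± 0.12 and that for S6 (Cre12.g558000) went from 12.5 to 37.4. In contrast, the gene for plastid-specific ribosomal protein 1 (Cre05.g237450) fell from 333 ± 18.7 to 36.5 ± 8.41. The other lowered member is also described as a putative mitochondrial ribosomal protein (Cre12.g521250), with a log2 fold change of -0.82 ± 0.21. The 1 cytosolic ribosomal protein gene, an isoform of S27e (Cre02.g145250), fell from 42.6 ± 1.85 to 9.34 ± 1.43. Of the ribosome biogenesis genes Cre03.g197000 rose by a log2 fold change of 1.15 ± 0.08 and a pre-rRNA processing gene (Cre09.g411450) fell by 1.00 ± 0.16. In the cell cycle list 2 genes rose, 4 fell and 1, a CDT1-like replication factor, lay below the filter (adjusted p for direction = 0.653, exact test), with 6 past the threshold adjusted over the list alone. A ribonucleotide reductase subunit gene (Cre12.g509400), which supplies DNA precursors, rose from 57.1 ± 7.81 to 166 ± 3.95. An L-type cyclin gene (Cre07.g321650) rose from 17.7 ± 2.16 to 52.2 ± 4.65, and CDKG1 (Cre06.g271100), a cyclin-dependent kinase gene, fell from 98.8 ± 9.55 to 45.0 ± 4.73. In the list of cilia and flagella genes 9 of 16 rose and 7 fell (adjusted p = 1, exact test). The flagellar associated protein genes with the smallest p-values fell, namely g11461, from 302 ± 11.6 to 43.7 ± 6.06, Cre17.g708000, from 246 ± 7.81 to 84.2 ± 4.56, and Cre16.g652350, from 23.1 ± 2.08 to 4.03 ± 0.744. The cell wall list had 5 lowered genes of 7 (adjusted p = 0.448, exact test), among them pherophorin-C5 (Cre05.g238650), from 528 ± 26.7 to 206 ± 18.0, pherophorin-C4 (Cre12.g549000), from 94.3 ± 14 to 46.5 ± 4.21, and g15607, from 166 ± 21.4 to 82.8 ± 11.8. Single genes of a histone H3 variant (Cre16.g661450) and of autophagy (g3389) fell by 1.01 and 0.94 on the log2 scale. A gamete-specific protein gene (g16725) fell by 1.41, and a homeobox gene of the gamete list (Cre02.g109650) rose by 0.99 ± 0.20. The Calvin-Benson cycle and circadian clock lists had 0 annotated members. In every list with members the count past the threshold over all genes equalled the count adjusted over the list alone.

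The authors' deposited table, made from the same libraries, lists 2596 genes changed more than 2-fold, 1301 as induced and 1295 as repressed. Of these, 2588 entered the test here, 2585 passed the threshold in the direction listed, and 0 had the opposite direction. Of the 2585, 1749 had at least a 2-fold change on the log2(value + 1) scale, and 2 genes with at least a 2-fold change here were absent from the authors' deposited table. With edgeR on the recovered reads, 1299 genes were raised and 1286 lowered at least 2-fold, near the 1301 and 1295 of the authors' deposited table. Another 5335 genes passed the adjusted p of 0.05 here without being in that table. Across the shared genes the log2 fold changes had a Pearson r of 0.980 and a Spearman rho of 0.946, where genes are not independent replicates and both values come from the same 6 libraries. For PSBS1 the log2 fold change in the authors' deposited table is 10.06, for LHCSR1 it is 2.94, and for the hydrogenase assembly factor Cre06.g296700 it is -4.57.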

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

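The list membership by symbol alone and the settings for the counts were planned, and the test of list direction was chosen after the annotation was seen. The number of genes changed by UV-B ran from 6396 with a minimum value of 5, where fewer genes are tested, to 8102 with the replicate block, and 80.01% to 100% of the 7920 genes kept their call and direction in each refit. Leaving out 1 library in turn gave 7242 to 7565 genes. A pseudocount of 5 moved the genes raised and lowered at least 2-fold to 453 and 489, since it shrinks the fold of low genes, and edgeR on recovered reads gave the highest counts, 1299 and 1286. Scaling to an equal total raised the median log2 fold change of all genes by 0.09 and gave 4533 raised and 3187 lowered genes. All 75 named genes kept their direction and stayed past the threshold wherever they were tested. For the direction of the light stress list, membership by symbol alone gave a difference of 46.0 percentage points, past the threshold with an adjusted p of 0.00258 (0.00258 to 0.203 over the alternatives, Fisher's exact test), because the 1 lowered gene has no symbol and only 1 list then has 5 members to adjust over. Among the other settings no list direction passed. In the DNA repair list the difference of 2.72 points ran from 2.53 to 22.9 over the alternatives. Its lowest adjusted p was 0.355 (Fisher's exact test). In the cilia list the difference of 1.82 points became -7.46 with a minimum value of 5, and in the lipid list -4.49 became 9.40 there, 2.62 without UV-B replicate 2 and 2.76 with DESeq2, none past the threshold. Whether replicate numbers pair the libraries was not settled. Deviations of same-numbered libraries correlated weakly, at 0.045, 0.024 and 0.12, and those of differently numbered libraries at -0.1007 to 0.0601. Not every library correlated best with its own number. On the second principal component, however, replicate 3 of both groups lay on the opposite side from all other libraries. A weak effect shared by replicate number is thus not excluded. The block moved the count of calls from 7920 to 8102. It changed no other call of a list or named gene. Camera with a preset or an estimated correlation and fry were not run.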

Other observations

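The functional categories and the anaerobic metabolism group, with the tests on them, were chosen after the data were seen. Predictions for the tests of joint variation across cultures, of neighbouring genes and of other splits were written before those tests were run. These tests were not part of the design fixed before the data were examined. Within the categories of the authors' deposited table, 33 had at least 8 genes past the threshold. These were compared for direction with the other categorised genes by Fisher's exact test, and 6 passed an adjusted p of 0.05. Categories were tested with the main fit only, so how these 6 calls depend on the settings is not known. The test counts genes as independent. Genes of a category can change together in the same 6 libraries, so these p-values may be too small. All 14 genes of amino acid activation, whose subcategory names are mostly those of enzymes that load transfer RNAs, rose (adjusted p = 0.00266), as in a glutamyl/glutaminyl-tRNA synthetase gene (g11477) that went from 10.6 to 22.2. Amino acid degradation went the other way, with 14 of 15 genes lowered (adjusted p = 0.00266), among them the alpha subunit gene of methylcrotonoyl-CoA carboxylase (g6242), an enzyme of leucine breakdown, with a log2 fold change of -2.43 ± 0.08. Major carbohydrate categories went down, with 10 of 10 genes lowered in degradation (adjusted p = 0.00358) and 9 of 10 in synthesis (adjusted p = 0.0482). They are mostly genes of starch, but the former includes acetate kinase (Cre09.g396700) and phosphate acetyltransferase (Cre17.g699000), which also belong to the anaerobic group below, and the latter includes a gene of sucrose synthesis (Cre06.g283400). A granule bound starch synthase gene (Cre06.g257050) rose, by a log2 fold change of 0.91. Lowered starch genes are a starch phosphorylase gene (Cre12.g552200), which went from 104 to 27.4, an alpha-glucan water dikinase gene (Cre07.g319300), from 37.6 to 6.26, and the gene for soluble starch synthase III (Cre13.g579600), from 34.9 to 11.3.

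Lipid degradation had 11 lowered genes and 2 raised (adjusted p = 0.0482), including a triacylglycerol lipase gene (Cre03.g193500) that went from 221 to 85.7. Posttranslational modification, a category whose described members are mostly protein kinases and phosphatases, had 57 lowered and 26 raised genes (adjusted p = 0.000805), with a mitogen-activated protein kinase kinase kinase gene (Cre12.g545950) at -2.42 ± 0.13 and a phosphoprotein phosphatase 2C gene (Cre17.g715700) at 1.90 ± 0.11. The light reactions of photosynthesis had 19 raised and 5 lowered genes but did not pass (adjusted p = 0.0567). The lowered genes include the hydrogenase assembly genes Cre06.g296700 and Cre06.g296750, which also belong to the anaerobic group below. They also include Cre07.g350750, described as an alternative oxidase and placed under chlororespiration. As with the lists, these categories cover genes the authors had called, so they speak of direction and not of how much of a pathway responded.

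Genes of fermentation and hydrogen metabolism were lowered in all 13 annotated cases, with a median log2 fold change of -3.0. The group was put together after falls among its members were seen, so its direction was not tested. Beside the hydrogenase assembly genes, they include an iron hydrogenase gene (Cre03.g199800), from 442 ± 9.06 to 70.4 ± 7.08, and HYDA2 (Cre09.g396600), from 97.6 ± 4.96 to 28.0 ± 1.37. Others are pyruvate-formate lyase PFL1 (Cre01.g044800), from 707 ± 3.27 to 132 ± 14, pyruvate-ferredoxin oxidoreductase (g1910), from 79.8 ± 2.89 to 8.14 ± 2.12, and a dual-function alcohol and acetaldehyde dehydrogenase (g18056), from 97.9 ± 2.35 to 10.5 ± 0.956. The median stayed at -2.92 or lower without any 1 of the 6 libraries, and the highest median among 4 other scalings was -2.92. The fall thus did not rest on 1 library or on the scaling used. Both checks were chosen after the values were seen, on genes already listed as changed in these libraries. They could hardly have come out otherwise, so they are no test of a culture out of step or of the scaling. These genes are used when oxygen is low, so a candidate explanation is that oxygen differed between dishes. Deviations of these genes from their group means had a mean pairwise correlation of 0.34, at percentile 93.2 of 2000 lists of lowered genes of like level (5% to 95% range -0.013 to 0.36), which leaves that explanation open. A difference in oxygen that follows the filter, through light reaching photosynthesis or respiration, cannot be told apart from a direct response to UV-B, since no oxygen was measured in the data used here.

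Neighbouring genes changed alike more often than chance. In the RefSeq gene order, log2 fold changes of 7062 pairs with 0 genes between them correlated at a Pearson r of 0.138 and a Spearman rho of 0.131 across genes, where 1000 shuffled orders gave -0.036 to 0.038 (permutation p = 0.001, the smallest these shuffles can give; adjusted p = 0.0060 over 6 distances). Of 176 such pairs with both genes changed at least 2-fold, 120 (68.2%) shared their direction, as with LHCSR2 and LHCSR3 and with the hydrogenase assembly genes. Reads assigned to the wrong member of a pair may produce this, as this predicts likeness only with 0 genes between: with 1 gene between, r was 0.027, inside the shuffled range of -0.048 to 0.049, although its permutation p was 0.032 (adjusted p = 0.048). With 2 genes between, r was 0.034 (permutation p = 0.006, adjusted p = 0.018), inside a shuffled range of -0.045 to 0.039, and 60.4% of 2-fold pairs shared direction, while with 4 between r was -0.030 (permutation p = 0.03, adjusted p = 0.048). Weak likeness at spacings of 1 and 2 genes would count against misassigned reads as the whole cause. These r lie inside the shuffled ranges, and r at 4 is of like size with the opposite sign, so the explanation stays open. Tandem copies and shared promoters predict the same decay and were not tested, and 56 of the 176 pairs moved in opposite directions.

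Other splits of the 6 libraries into groups of 3 were tried for the count of changed genes. The real split gave 7920 genes and the highest of the others gave 0 with limma. Every other split mixes UV-B and no UV-B libraries within each group. The difference between treatments then counts as spread within groups, so few or no calls were bound to come from these splits. Their 0 calls therefore do not show how many genes would be called without an effect of UV-B, and no conclusion is drawn from them. With 10 splits, of which 1 gave as many as the real one, the share cannot fall under 0.05.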
